A study of Mus musculus with 6 samples.

How the data were processed

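Poly(A)-selected RNA from salivary gland primordia of wild-type mice at embryonic day 13.5 was sequenced in 6 libraries, 3 given 0 and 3 given 300 ng/ml BMP-2. The length of the treatment is not given in the labels. Per the labels' protocols, RNA was isolated with a small-input column kit and libraries were made with a directional kit. The table deposited by the authors holds raw whole-number read counts per gene, with no normalization, for 58116 features, of which 53519 have Ensembl gene identifiers and 4597 are unnamed gene models, which hold 0.296 to 0.366% of the counts of a library. Per the submitters' processing notes, the tools were cutadapt 2.9, HISAT2 2.2.0 and featureCounts, and the genome build was GRCm39. Whether strand was used in counting, and how reads matching several places were counted, is not given in the sources used here, so genes with antisense or overlapping partners and near-identical copies are uncertain. Rows for nuclear copies of mitochondrial sequence on chromosome 1 hold 2.30 to 3.05% of a library, so mitochondrial reads may be split between places. The reference at hand is of another build and was not used, so coordinates are those of the deposited table.

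Groups came from the labels for 5 columns of the table, where the name matched the description of 1 sample. The name of the remaining column matched no description, and 1 BMP-2 sample matched no column. The group of this column was inferred only from its first letter, which begins the descriptions of the BMP-2 samples alone. It was used as a BMP-2 replicate without a number and is called the unnumbered BMP-2 library. Replicates were compared before use, and all pairs differed by far more than sampling noise (chi-square per degree of freedom from 13.7 to 41.5), so each counted as a separate library.

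From the counts, the main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3; robust fit, TMM factors, default expression filter by group), with Benjamini-Hochberg adjustment over 17006 genes and a threshold of 0.05. With 3 libraries against 3 the model has 4 residual degrees of freedom, the common biological coefficient of variation was 0.214, and an exact permutation test of 1 value cannot give a two-sided p under 0.1. CPM values are counts scaled by library size and TMM factor, given as mean ± SD. For the genes with 1 to 3 control counts, ratios carry an exact 95% interval that covers counting error only. Before the data were examined, 36 gene lists of pathways, cell types and states, the alternatives and the rule for named genes were fixed. Lists were tested with camera (limma 3.58.1, preset correlation 0.01, adjusted over the 36 lists), again with an estimated correlation, and with fry, which asks whether the genes of a list move on balance in 1 direction. A list score is the mean log2 CPM of its members (prior count 2) relative to the control libraries. For 5 listed symbols no row was found, and these genes were not analysed here.

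The named genes are Bmp2, Id1, Id2, Id3, Smad6, Smad7 and Msx2, whatever their result; the 12 called genes with the largest rise and the 12 with the largest fall that separate the groups, have a mean of at least 2 CPM and are not unnamed models; up to 4 called genes of each list by adjusted p, or its 2 most abundant members where none was called; and the 5 genes with the lowest adjusted p. Members of lists with no result are not all named. Other genes named in the text were chosen after their values were seen and are marked so.

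On simulated data with the means, dispersions and library sizes of these libraries (16750 genes tested), the edgeR script recovered 55.1% of 2-fold and 90.9% of 4-fold changes, all in the simulated direction, with 12 false calls among the unchanged genes. Camera called the simulated list of 20 genes moved 1.5-fold and 0 of 30 unchanged lists, and with an estimated correlation it did not call the moved list. The simulated genes were drawn independently, so this does not show how often camera calls lists whose genes vary together. In the real libraries the estimated correlation was 0.363 for the BMP/SMAD response list and 0.826 for the skeletal muscle list. Alternatives covered the scaling (DESeq2 size factors, upper quartile, library totals), the low-count filter, the test (DESeq2 1.42.0, limma-voom, edgeR without the robust option, a test against a 1.5-fold change), a stricter threshold, a replicate block and leaving out each library.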

Results

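Gene expression was measured by poly(A) RNA sequencing in salivary gland primordia of wild-type mouse embryos at embryonic day 13.5, when the gland is a small branching epithelium within mesenchyme. The primordia had been given 0 or 300 ng/ml of BMP-2, a secreted ligand of the bone morphogenetic protein family that signals through receptor kinases and SMAD proteins. The labels do not say how long they were treated, so direct and later changes cannot be told apart. Each group had 3 libraries, and the question was how the ligand acts on the forming gland. Total counts were 21150072, 19724383 and 26269855 in control replicates 1, 2 and 3. They were 32473558 in BMP-2 replicate 1, 23970044 in BMP-2 replicate 2 and 23331703 in the BMP-2 library that carries no replicate number, and did not separate the groups (n = 3 each; exact two-sided permutation p = 0.4). The 50 most abundant genes took 15.2 ± 1.32% of the counts without and 14.5 ± 0.890% with BMP-2 (SD, n = 3 each; exact two-sided permutation p = 0.6), and mitochondrially encoded genes took 2.29 ± 0.181% and 2.24 ± 0.276% (p = 0.8 in the same exact test). Only 3 of the 13 mitochondrially encoded mRNAs passed the expression filter, so reads of the others may be missing or counted in other rows, and the share may not measure all mitochondrial RNA. Nothing states whether the libraries of a group came from separate litters or cultures, so the p-values below measure the spread between these libraries, which may be partly technical.

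BMP-2 changed 155 of 17006 tested genes (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05): 138 were higher and 17 lower with BMP-2, and 133 of the 155 had an absolute log2 fold change of at least 1. Among the genes that rose were 12 of 20 BMP/SMAD response genes and 7 cartilage or bone genes, with Dlx5 in both counts. The lowest adjusted p belonged to Aspn, which encodes asporin, a small leucine-rich matrix proteoglycan: 19.2 ± 1.64 CPM (counts scaled to library size) without and 103 ± 15.6 CPM with BMP-2 (SD, n = 3 each), a log2 change of 2.42 (SE 0.14, adjusted p = 0.00125). Ogn, which encodes the related matrix protein osteoglycin, rose by 2.43 on the log2 scale (SE 0.189) and the potassium channel tetramerisation domain gene Kctd12 by 1.28 (SE 0.0984), both with an adjusted p of 0.00482. Gja3, a gap junction gene, and Unc5b, a netrin receptor gene, followed with log2 changes of 3.78 and 1.65, both with an adjusted p of 0.00599. These 5 genes remained called whichever single library was left out, as did Nog, Col9a2, Postn, the lower gene C1s1 and 3 genes chosen after their values were seen, Edil3, Krt24 and Lipk. The other calls were less firm. Fits without control replicate 1, 2 or 3 called 20, 21 and 151 genes, among them 19, 16 and 84 of the 155. Fits without BMP-2 replicate 1, BMP-2 replicate 2 or the unnumbered BMP-2 library called 94, 135 and 29 genes, among them 73, 87 and 28 of the 155.

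The BMP/SMAD response genes, a list of 20 known targets and feedback genes, had the lowest adjusted p of the 36 lists tested. Of its 20 members 12 rose, none fell, and all 20 had a positive log2 change, with a median of 1.74; adjusted over the list alone, 19 rose. Id1 and Id3, inhibitors of basic helix-loop-helix transcription factors and classic BMP targets, rose 3.58-fold and 3.41-fold, Id1 from 25.6 ± 4.09 to 91.6 ± 27.9 CPM and Id3 from 34.9 ± 6.33 to 119 ± 37.8 CPM (SD, n = 3 each; adjusted p = 0.0245 and 0.0298, edgeR). Msx2, a homeobox gene, rose from 0.191 ± 0.166 to 14.2 ± 7.80 CPM, a log2 change of 6.08 (SE 0.732, adjusted p = 0.0205). A pair of feedback genes also rose, Smad6, an inhibitory SMAD, by 1.30 on the log2 scale (SE 0.215) and Nog, which encodes the secreted BMP antagonist noggin, by 3.64 (SE 0.348). The other called members were Smad9, Atoh8, Dlx3, Dlx5, Hey1, Gata2 and Gata3, with log2 changes from 1.71 for Gata3 to 4.55 for Dlx3. Id2 and Smad7 were not called, with log2 changes of 0.62 (adjusted p = 0.193) and 0.68 (adjusted p = 0.183) in edgeR, and Bmp2 itself was at 2.25 ± 0.638 CPM without and 2.52 ± 0.735 CPM with the added protein (SD, n = 3 each; adjusted p = 0.972, edgeR). As a group the list stood above the other genes (camera, adjusted p = 1.43e-60), but not when the correlation between its genes was estimated (adjusted p = 0.105 with an estimated correlation). The list held 19 called genes by DESeq2 and 5 by limma-voom, 2 without control replicate 1, 1 without control replicate 2 and 3 without the unnumbered BMP-2 library. Id1 lies on chromosome 2 from 152578171 to 152579330 and Msx2 on chromosome 13 from 53620920 to 53627110 (GRCm39, whole gene spans).

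**Figure D1:**
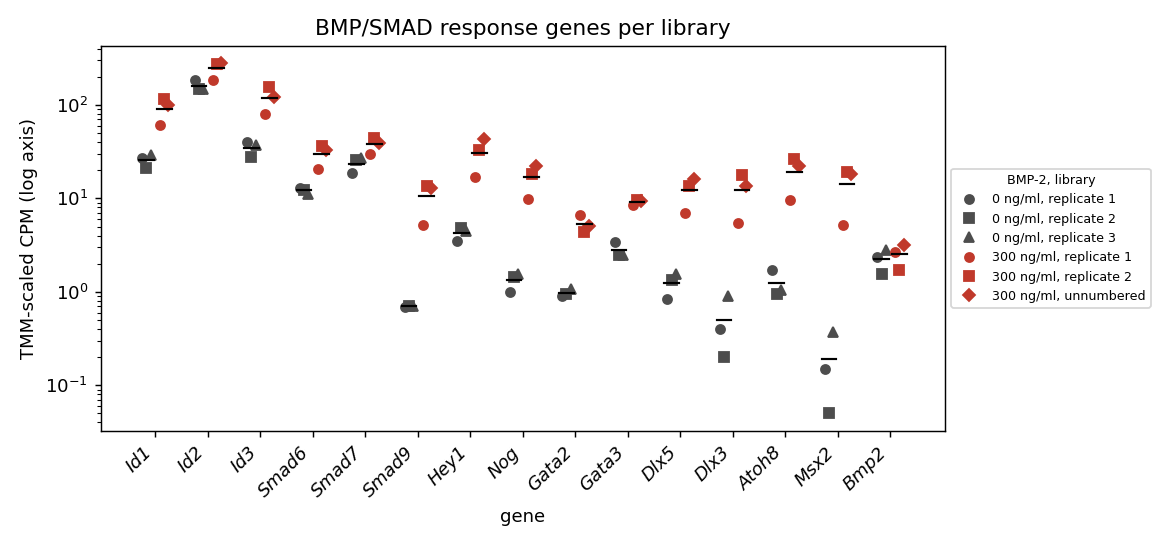
TMM-scaled CPM (log axis) of 15 BMP/SMAD response genes in each of the 6 libraries, grey for 0 and red for 300 ng/ml BMP-2, with black bars at the group means. Msx2 has means of 0.191 and 14.2 CPM, and Bmp2 overlaps between the groups.

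Some genes of other signalling pathway lists rose with BMP-2, among them ligands, receptors and secreted inhibitors. Most members of these lists were not called, and secreted inhibitors were not tested as a list. Hey1 and Nog are also BMP/SMAD response genes, and Wif1 is in both Wnt lists. Wif1, a secreted Wnt inhibitor, rose from 0.827 ± 0.353 to 35.2 ± 16.3 CPM (SD, n = 3 each), a log2 change of 5.36 (SE 0.483, edgeR adjusted p = 0.00966). Notum, a secreted enzyme that inactivates Wnt proteins, rose by 2.11, the Wnt ligand gene Wnt5a by 2.56, the Wnt signal enhancer gene Rspo2 by 1.76 and Dkk3 by 0.73. Thus 2 of 12 canonical Wnt response genes and 4 of 22 Wnt ligand and inhibitor genes rose and none fell. Adjusted over the list alone the counts were 4 and 5. Uncalled negative changes were found in 5 of the 12 and 8 of the 22. Limma-voom called 2 Wnt ligand and inhibitor genes; whichever single library was left out, edgeR called at most 2, and 0 without control replicate 1. Both Wnt lists were called by camera (adjusted p = 3.71e-06 and 1.85e-05) and both had an adjusted p = 0.148 with an estimated correlation. Among 31 BMP ligands, receptors and antagonists, Nog, Bmp5 (log2 change 2.41) and Bmper (1.69), a BMP-binding endothelial regulator, rose, and 28 were not called; 5 rose adjusted over the list alone. Camera called this list (adjusted p = 0.00823; adjusted p = 0.176 with an estimated correlation), but not without BMP-2 replicate 1 (adjusted p = 0.0909), on limma-voom values (0.0943) or with the skeletal muscle score as a covariate (0.111). The receptor gene Fgfr3 was the 1 called member of 15 FGF ligand and receptor genes (log2 change 1.27, SE 0.196), with 3 adjusted over the list alone. Hey1 was the 1 called member of 14 Notch pathway genes, with 2 adjusted over the list alone, and Erbb4 the 1 called member of 12 EGF family genes, with 1 adjusted over the list alone (log2 change 2.73, from a level of 0.187 ± 0.0819 CPM, SD, n = 3). The Notch list was called by camera (adjusted p = 0.00280; adjusted p = 0.176 with an estimated correlation, 0.241 with the muscle covariate) and the EGF list was not (adjusted p = 0.454).

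Some cartilage and bone genes rose with BMP-2. Of 17 cartilage genes, Col2a1, Acan, Col9a2 and Matn4 rose, 13 were not called, and adjusted over the list alone 10 rose and 1 fell. Col2a1, the main fibrillar collagen gene of cartilage, rose from 1.19 ± 0.594 to 26.4 ± 13.7 CPM (log2 change 4.44, SE 0.508, adjusted p = 0.0170), and Acan, the large cartilage proteoglycan gene, from 0.208 ± 0.137 to 8.48 ± 4.06 CPM (log2 change 5.38, SE 0.573, adjusted p = 0.009996; SD, n = 3 each, edgeR). Col9a2 was already at 50.02 ± 4.02 CPM without BMP-2 and rose 2.24-fold. Of 11 bone genes 3 rose, and 6 rose and 1 fell adjusted over the list alone. Sp7, which encodes the osteoblast transcription factor osterix, had 1 count in the control libraries together and 599 in the BMP-2 libraries, a ratio of 504 with a 95% counting interval from 90.1 to 19946. Dlx5, which is also a BMP/SMAD response gene, rose by 3.26 on the log2 scale. Col10a1, the collagen gene of hypertrophic cartilage, rose by 2.97 (adjusted p = 0.0483, edgeR). Its level was low, 0.117 ± 0.0578 CPM without and 0.971 ± 0.273 CPM with BMP-2 (SD, n = 3 each). Col10a1 overlaps Nt5dc1 on the other strand, and their reads cannot be told apart if strand was not used in counting. Alkaline phosphatase Alpl had a log2 change of 3.96 but was not called (adjusted p = 0.0647, edgeR), and the master regulators of the lineages, Runx2 and Sox9, had log2 changes of 0.09 and -0.05. Alpl, Runx2 and Sox9 were chosen after their values were seen. Sox9 is also in the end bud and FGF/ERK response lists and had a mean of 169 CPM, so a rise in few cells may not show in it. Camera called both lists (adjusted p = 1.12e-13 for cartilage and 1.10e-10 for bone), and with an estimated correlation the adjusted p was 0.148 and 0.176. DESeq2 called 10 cartilage and 5 bone genes and limma-voom 2 and 0. Without control replicate 1 the called genes of the lists fell to 2 and 0, without control replicate 2 to 1 and 0, without control replicate 3 to 3 and 1, and without the unnumbered BMP-2 library to 3 and 1. Skeletal muscle transcripts, described next, were also higher in the BMP-2 libraries.

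Of 18 mesenchymal fibroblast genes 2 rose, Postn, a matrix protein gene, from 326 ± 37.5 to 814 ± 45.5 CPM (SD, n = 3 each; log2 change 1.32, SE 0.124, edgeR adjusted p = 0.00778) and the homeobox gene Meox2 by 2.08 on the log2 scale; 5 rose adjusted over the list alone. Camera called the list upward (adjusted p = 0.000526; adjusted p = 0.318 with an estimated correlation), while 8 of its 18 members had a negative change. Fabp4, a fatty acid binding protein gene of fat cells, was the 1 called member of 12 adipogenic genes (log2 change 2.16, SE 0.360), with 4 adjusted over the list alone (camera adjusted p = 3.71e-06; adjusted p = 0.176 with an estimated correlation). Muscle transcripts, described next, moved with both lists. In control replicates 1, 2 and 3 the mesenchymal score was -0.03, -0.096 and 0.13 and the adipogenic score 0.13, -0.64 and 0.51, highest in the control with most muscle transcripts. In BMP-2 replicates 1 and 2 and the unnumbered library the scores were 0.45, 0.15 and 0.49 and 1.196, 0.73 and 1.16, lowest in the treated library with least muscle transcripts. With the muscle score as a covariate neither list was called (adjusted p = 0.951 and 0.201). The order of the controls and the lost calls are not particular to these 2 lists. Control replicate 3 also had the highest control score for BMP/SMAD response genes (0.13) and leukocyte genes (0.62). The covariate also ended every call of a single gene.

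Skeletal muscle transcripts differed strongly between libraries. All 13 tested members of the muscle list had positive log2 changes with a median of 4.23, and camera called the list (adjusted p = 1.33e-15; adjusted p = 0.176 with an estimated correlation). Pax7, a transcription factor gene of muscle progenitors, was the 1 called member, with 3 counts in the control and 145 in the BMP-2 libraries, a ratio of 40.7 (95% counting interval from 13.6 to 200); 10 rose adjusted over the list alone, DESeq2 called 5, and the replicate block on 4 libraries called 11. Pax7 was still called without BMP-2 replicate 2, but not when any other library was left out (adjusted p from 0.0641 to 0.102, edgeR). The sizes depend on control replicate 3. Without it edgeR called 2 members, and Myog, Actc1 and Ttn, chosen after their values were seen, had log2 changes of 10.5, 10.9 and 8.08. With all libraries these were 3.92, 4.27 and 4.09. The cardiac and slow muscle myosin gene Myh7 was also called (log2 change 4.29, SE 0.616); it overlaps antisense transcripts, and its reads cannot be told from theirs if strand was not used in counting. The list score, the mean log2 CPM of its members relative to the control mean, was -1.54, -1.0003 and 2.54 in control replicates 1, 2 and 3, and 5.65, 3.73 and 5.73 in BMP-2 replicates 1 and 2 and the unnumbered library. The sarcomeric actin gene Actc1, chosen after its values were seen, was at 23.2 CPM in control replicate 3 and at 0.150 CPM or less in the other 2 controls, and at 215, 44.0 and 211 CPM with BMP-2. With the list score as a covariate, an alternative added after the data were seen, edgeR called 0 genes. An unadjusted p below 0.05 was found for 352 of 17006 genes in edgeR, against 1721 without the covariate. The 352 are a smaller share than the 0.05 that unchanged genes alone would give. They held 116 of the 155 and all 12 called BMP/SMAD response genes, which had been picked as changed in these same libraries. All 155 kept the sign of their change. Their median absolute log2 change was 2.11 without and 1.83 with the covariate, and the median SE 0.296 and 0.598.

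**Figure D2:**
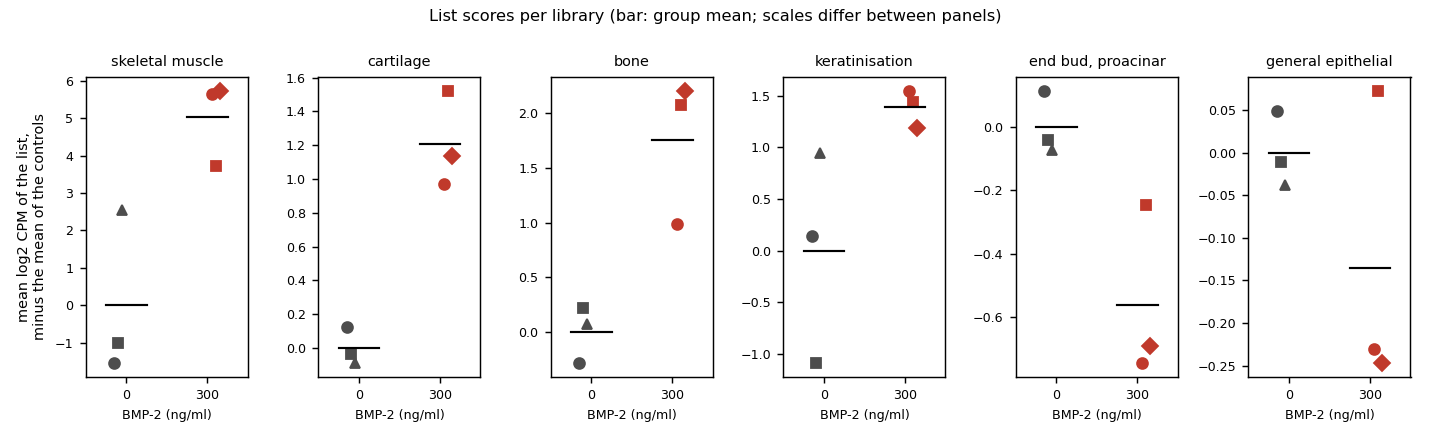
Score of 6 gene lists in each library (mean log2 CPM of the members, relative to the mean of the control libraries), grey for 0 and red for 300 ng/ml BMP-2: circles replicate 1, squares replicate 2, triangle control replicate 3, diamonds the unnumbered BMP-2 library, bars the group means. Control replicate 3 has a muscle score of 2.54 against -1.54 and -1.0003 in the other controls, and the general epithelial score overlaps between the groups.

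Among the epithelial lists, camera called the keratinisation genes upward and the end bud and proacinar genes downward, but neither with an estimated correlation (adjusted p = 0.181 and 0.176), and edgeR called 0 members of either. Of 28 keratinisation and squamous genes 24 had a positive log2 change, with a median of 1.05, 9 rose adjusted over the list alone, and 13 were higher at an unadjusted p below 0.05 (edgeR). DESeq2 called 7 members of the list, limma-voom 1, the replicate block 11, and edgeR 3 and 4 without control replicate 2 or 3. Krt6a was at 561 ± 290 CPM without and 1486 ± 461 CPM with BMP-2 (SD, n = 3 each; log2 change 1.40, adjusted p = 0.199), and Dsp, a desmosome gene, had a log2 change of 0.62 (adjusted p = 0.257, edgeR). The camera adjusted p of the list was 1.24e-13. Its score was 0.94 in control replicate 3, the control with most muscle transcripts, and 0.15 and -1.09 in the other 2 controls. Among the treated libraries it did not follow muscle. In BMP-2 replicates 1 and 2 and the unnumbered library it was 1.55, 1.44 and 1.19, against muscle scores of 5.65, 3.73 and 5.73. Of 16 end bud and proacinar genes 15 had a negative change, with a median of -0.34 (camera adjusted p = 7.93e-07). At an unadjusted p below 0.05, 7 were lower in edgeR, DESeq2 called 2 lower and limma-voom 0, and 3 fell adjusted over the list alone: Bpifa2, a major secretory protein gene of the early gland, Lpo and Prol1, the latter pair chosen after their values were seen. Bpifa2 was at 2290.0 ± 967 CPM without and 829 ± 283 CPM with BMP-2 (SD, n = 3 each; log2 change -1.47, adjusted p = 0.141), Lpo had a log2 change of -1.59 (adjusted p = 0.0822) and Prol1 of -1.49 (adjusted p = 0.199, all edgeR). Reads of Dcpp1, another secretory gene (log2 change -0.35, adjusted p = 0.343), may be shared with its near-identical neighbours. General epithelial genes had a median of -0.11, with 0 called by edgeR, DESeq2 or limma-voom, 0 adjusted over the list alone and 0 at an unadjusted p below 0.05 in edgeR (camera adjusted p = 0.0448; adjusted p = 0.595 with an estimated correlation). This camera call ended without control replicate 1 (adjusted p = 0.188), BMP-2 replicate 1 (0.265) or the unnumbered library (0.249). Of 14 ductal genes only Gata3, which is also a BMP/SMAD response gene, was called, upward. Of the 14, 11 had a negative change and the median was -0.24. Adjusted over the list alone 1 rose and 2 fell. Camera called the list downward (adjusted p = 0.0408), but not with an estimated correlation (adjusted p = 0.420). The ductal call ended without control replicate 1 (adjusted p = 0.0733) or the unnumbered library (0.294). With the muscle score as a covariate the keratinisation and end bud lists were not called either (adjusted p = 0.163 for both).

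**Figure D3:**
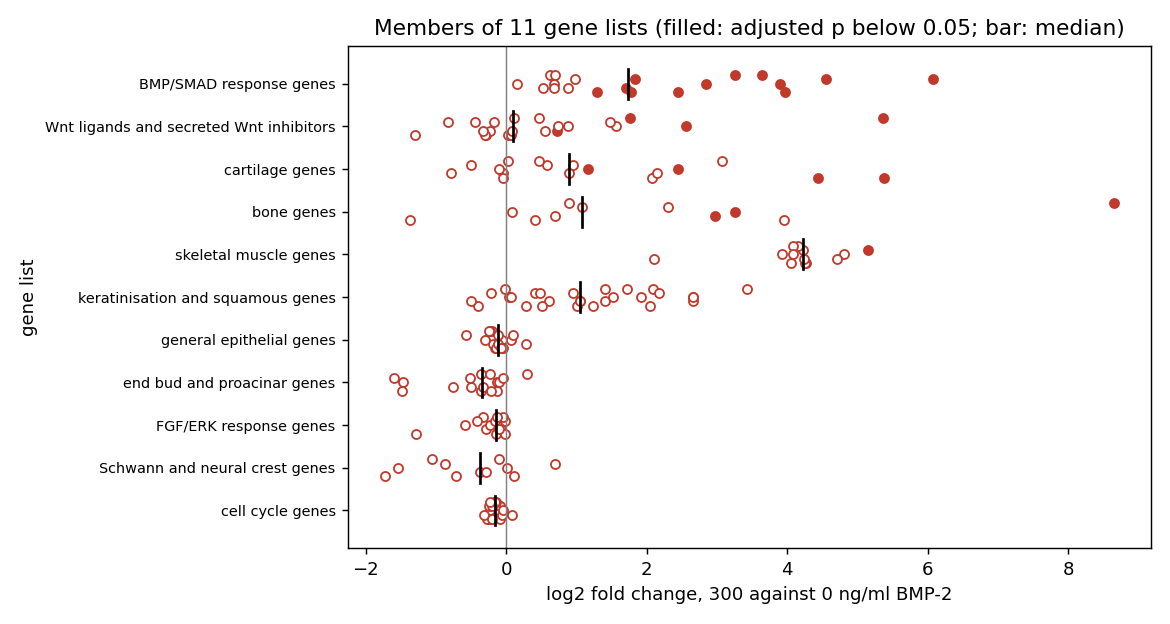
Log2 fold change (300 against 0 ng/ml BMP-2) of each tested member of 11 gene lists, filled where the gene was called at an adjusted p below 0.05, with a black bar at the list median. The medians run from 4.23 for skeletal muscle genes to -0.38 for Schwann and neural crest genes, and BMP/SMAD response genes have 12 filled points.

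Among the called genes with a mean of at least 2 CPM, the largest rises beyond those named were in Krt84, a hard keratin gene (log2 change 7.28, SE 0.879), Tnn, which encodes the matrix protein tenascin-N (6.89, SE 0.959), Cxcl14, a chemokine gene (5.77, SE 0.503), Tbx20, a T-box gene (5.11, SE 0.597), and Cyp26b1, which degrades retinoic acid (4.28, SE 0.399). Cxcl14 went from 1.19 ± 0.163 to 65.6 ± 32.6 CPM (SD, n = 3 each). The 17 genes that fell had smaller changes. Cnga3, a cyclic nucleotide-gated channel gene, fell by 2.54 on the log2 scale (SE 0.435) and the orphan receptor gene Gpr50 fell by 2.50 (SE 0.305). Fstl5, Col6a5, Vstm2a and Scg2, the last encoding a neuroendocrine secretory granule protein, had log2 changes of -2.11, -2.07, -1.80 and -1.70. The complement protease gene C1s1 fell from 81.4 ± 8.10 to 34.3 ± 4.56 CPM (SD, n = 3 each; log2 change -1.25, SE 0.131, edgeR adjusted p = 0.00966). Gpr17, Myorg, Scara5, Ddah1 and Pde3a had log2 changes between -1.27 and -0.69. The number of genes called lower was 6 without control replicate 3, 1 without control replicate 1, 1 without control replicate 2 and 2 without the unnumbered BMP-2 library.

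Camera called the neuronal, Schwann and neural crest, FGF/ERK response and cell cycle lists downward, but none of them with an estimated correlation (adjusted p = 0.393, 0.175, 0.217 and 0.454), and edgeR called 0 of their members. At an unadjusted p below 0.05, 6, 5, 3 and 2 members were lower in edgeR and 1, 1, 0 and 0 higher; DESeq2 called 2, 0, 1 and 0 lower and limma-voom 0 in each. Of 16 neuronal genes 13 had a negative change (median -0.51, 1 lower adjusted over the list alone), among them Stmn2 with -0.89 (adjusted p = 0.280) and Prph with -0.64 (adjusted p = 0.602, edgeR). The neuronal score was -1.12 in BMP-2 replicate 1 and -0.38 in the unnumbered library, but -0.076 in BMP-2 replicate 2, within the controls (-0.15 to 0.24). Of 11 Schwann and neural crest genes 8 had a negative change (median -0.38), and 5 fell adjusted over the list alone. The camera adjusted p of these lists was 2.57e-05 and 0.000745. All 15 FGF/ERK response genes had a negative change (median -0.14, 1 lower adjusted over the list alone; camera adjusted p = 0.00102), as did 21 of 22 cell cycle genes (median -0.15, 0 adjusted over the list alone; camera adjusted p = 0.00144). The proliferation markers Mki67 and Top2a had log2 changes of -0.32 (adjusted p = 0.208) and -0.20 (adjusted p = 0.659, edgeR). The cell cycle call ended without BMP-2 replicate 2 (adjusted p = 0.166).

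In all, camera called 25 of 36 lists, 17 upward and 8 downward, and 0 with an estimated correlation. With the preset correlation it also called 5 to 15 lists in other splits of the 6 libraries into 3 and 3. Of the 25 calls, those not yet described each ended when some single library was left out. Upward they were the FGF ligand and receptor genes (adjusted p = 0.0182, and 0.0708 without control replicate 3 or 0.0909 without BMP-2 replicate 1), the TGF-beta and activin response genes (0.00823, and 0.262 without control replicate 1 or 0.285 without BMP-2 replicate 2), and the leukocyte genes (0.000658, and 0.0759 without control replicate 1 or 0.0572 without BMP-2 replicate 2). With an estimated correlation their adjusted p was 0.176, 0.420 and 0.420. All 14 leukocyte genes had a positive change, with 0 called by edgeR, DESeq2 or limma-voom, 0 adjusted over the list alone and 1 at an unadjusted p below 0.05 in edgeR; Lyz2, a macrophage gene, had a log2 change of 0.67 (adjusted p = 0.561, edgeR). Smooth muscle and pericyte genes (camera adjusted p = 0.0229), p53 and apoptosis genes (0.0217) and immediate early and heat shock genes (0.0408) were also called upward, and basement membrane genes (0.0337) downward; their adjusted p was 0.345, 0.420, 0.595 and 0.176 with an estimated correlation. Leaving out 1 library raised these 4 values to as much as 0.243 (without BMP-2 replicate 2), 0.123 (without BMP-2 replicate 2), 0.871 (without control replicate 1) and 0.0682 (without the unnumbered library). The p53 target and cell cycle inhibitor Cdkn1a had a log2 change of 1.03 (adjusted p = 0.0919, edgeR). With the muscle score as a covariate the general epithelial (adjusted p = 0.201), ductal (0.947), leukocyte (0.947), basement membrane (0.259) and immediate early calls (0.430) also ended, and basal and myoepithelial genes were called upward (0.0269) and interferon genes downward (0.000413). The replicate block ended the FGF ligand and receptor (0.0821), ductal and general epithelial (0.174 for both), mesenchymal and basement membrane (0.0798 for both) and p53 calls (0.1704). Fry called 8 of the 25 lists: BMP/SMAD response, BMP ligand, FGF ligand, both Wnt, cartilage, Schwann and neural crest, and basement membrane genes, the last with the lowest adjusted p (0.00941). In the main camera test, hedgehog, ectodysplasin, EGF family, basal and myoepithelial, endothelial, erythroid, cell cycle inhibitor, matrix protease, hypoxia and glycolysis, interferon and mitochondrially encoded lists were not called, with adjusted p from 0.0542 for endothelial genes to 0.839 for erythroid genes.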

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

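The muscle covariate, the restriction to Ensembl genes, the omission of mitochondrial genes and the second block were chosen after seeing the data. Scaling by DESeq2 size factors, upper quartile or library totals gave 153, 150 and 128 changed genes, a stricter filter 141 and a non-robust fit 152, against 155; the median change of all genes stayed near 0. All 155 calls kept their sign in every setting that tested them (144 were tested under the stricter filter). Counts moved by over 1.5 times are given as changed, higher, lower and at least 2-fold genes: 552, 433, 119 and 345 with no low-count filter (31643 genes tested; 144 of the 155 kept); 695, 531, 164 and 455 by DESeq2 (155 kept); 78, 69, 9 and 72 by limma-voom (70 kept). An adjusted p below 0.01 left 20, 19 and 1, a test against a 1.5-fold change 54, and library totals 10 lower genes. The cause of the differences between tools was not tested. Leaving out 1 library gave 20 to 151 changed, 19 to 145 higher, 1 to 18 lower and 20 to 145 genes changed at least 2-fold; 12 of 155 were called in all 6 such fits, which have fewer libraries. Lists called ranged from 19 to 25; 14 of the 25 held in all 6 fits, and 5 others gained a call in some.

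The replicate numbers, 1 to 3 in both groups of the labels, do not establish pairs. The columns match 2 of them in both groups, with correlations of deviations of 0.428 and 0.137. The unnumbered library taken as replicate 3 had -0.067 with control replicate 3. The 0.428 of the replicate 1 libraries was the highest of all pairs between groups. Deviations from the group mean sum to 0 within each group. The correlations of these 2 libraries with the other libraries of the opposite group (-0.342 to -0.124) therefore had to be negative on balance. They are no separate evidence. On the second principal component (23.2% of the variance) the replicate 1 libraries lay at 42.0 and 36.3, and the others from -31.6 to -6.82. Something shared by the replicate 1 libraries is thus possible, and the main test, which has no block, does not model it. The replicate block on the 4 libraries of replicates 1 and 2 gave 540, 451, 89 and 403 genes (132 kept) and 20 lists. With the unnumbered library as replicate 3 the block gave 305, 260, 45 and 229 (141 kept). With the muscle score as covariate 0, 0, 0 and 0 genes and 15 lists were called. The score was higher in each BMP-2 library than in any control and had a correlation of 0.868 with the group. This fit can therefore hardly separate treatment from muscle content. The median absolute log2 change of the 155 went from 2.11 to 1.83, and the median SE from 0.296 to 0.598. The fit also has 1 residual degree of freedom less. Which of these ended the calls was not tested. For the 12 called BMP/SMAD response genes the median log2 change was 3.05 before and 2.81 after. Lists called numbered 0 with an estimated correlation and 8 by fry.

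Signs turned only for values uncalled in the main test or in the other fit. Leaving out 1 library gave log2 changes from -0.047 to 0.366 for Bmp2, from -0.00078 to 0.196 for Runx2 and from -0.108 to 0.044 for Sox9. With the covariate Bmp2 went to -0.69, Sox9 to 0.26 and Myog, Actc1 and Ttn, members of the score, to -1.03, -1.14 and -0.14; with the replicate block Runx2 went to -0.092. The camera direction turned with the covariate for hedgehog and leukocyte (adjusted p = 0.947), general epithelial (0.201), endothelial (0.0862), erythroid (0.565), skeletal muscle, the list of the score itself (0.137), hypoxia (0.177) and immediate early genes (0.430), and with the block for ectodysplasin (0.555), hypoxia (0.0593), interferon (0.278) and mitochondrial genes (0.872). It turned in some fits without 1 library for 6 lists, with adjusted p over these fits from 0.389 to 0.983 for hedgehog, 0.580 to 0.988 for ectodysplasin, 0.802 to 0.988 for erythroid, 0.0183 to 0.591 for hypoxia (0.0183, downward, without the unnumbered library), 0.0204 to 0.449 for interferon and 0.474 to 0.932 for mitochondrial genes. Of 1897 values of named genes under the alternatives 1472 kept direction and side of the threshold, 374 lost and 40 gained the call, and 11 turned. At this depth a gene such as Sp7, with 1 control count, has no firm fold.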

Other observations

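The tests in this part were chosen after the results were seen, as were the genes named. Of the distal-less homeobox genes outside the lists, Dlx1 and Dlx2 rose (log2 changes 1.5 and 2.77), while Dlx4 had a change of 1.86 without a call (adjusted p = 0.0962, edgeR). Of those in the BMP/SMAD response and bone lists, Dlx3 and Dlx5 rose (4.55 and 3.26) and Dlx6 had a change of 2.30 without a call (adjusted p = 0.0621). Single called genes that no list held include the keratin genes Krt24 (6.44) and Krt80 (0.87), the lipase genes Lipk (4.06) and Lipm (2.84), the protease inhibitor genes Cst6 (3.49) and Slpi (2.54), the transglutaminase gene Tgm5 (1.37), the retinol dehydrogenase gene Rdh12 (1.88) and the retinoid receptor gene Rxrg (2.53). They were picked from the called genes, and no pathway or tissue was tested with them. In the keratinisation list, which had 0 members called by edgeR and 7 by DESeq2, Krt10 and Ivl had log2 changes of 2.66 and 3.43 (adjusted p = 0.199 and 0.0790, edgeR). In the receptor family of Fgfr3, Fgfr4 had a log2 change of 2.999 without a call (adjusted p = 0.0749, edgeR). Among Schwann and neural crest genes, Gfra3, Foxd3, Fabp7 and Cdh19 had log2 changes of -1.73, -1.05, -0.88 and -0.71 and were lower when adjusted over that list alone. Of the 12 called BMP/SMAD response genes 11 were lowest, among the BMP-2 libraries, in replicate 1.

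Called genes lie next to each other in the genome more often than in permutations: 6 pairs of adjacent, non-overlapping tested genes changed in 1 direction, against a mean of 1.02 when calls were permuted among genes of similar expression (one-sided permutation p = 0.0007, 10000 permutations). The pairs are Aspn and Omd, Omd and Ogn, which form 1 cluster of matrix proteoglycan genes on chromosome 13 from 49697919 to 49777977, Dlx1 and Dlx2, Lipk and Lipm, Lox and Sncaip, and Slpi and Matn4. Slpi and Matn4 are 297 bp apart, and reads running past a gene end were not looked for. Why neighbours were called together was not tested.

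All 13 tested skeletal muscle genes had a higher mean with BMP-2 (median log2 change 4.23), 1 of them called. Without control replicate 3 edgeR called 2, and the log2 change of Actc1 went from 4.27 to 10.9. One explanation is muscle tissue carried along with the glands in differing amounts, since 1 source keeps its genes in 1 ratio. Over the 4 libraries with muscle transcripts, control replicate 3 among them (Actc1 at 23.2 CPM, Ttn at 12 CPM, Myog at 8.19 CPM and Myod1 at 2.32 CPM), they had a residual SD of 0.576 on the log2 scale after gene and library effects, and 0.359 for the 11 with at least 10 counts in each, a filter that itself removes genes low in that control. The filter removes Myf5 and Pax7, the called gene. Pax7 departs from the ratio: it had 1 count in control replicate 3 and 72 in BMP-2 replicate 1. The ratio of the 9 kept muscle genes that are not transcription factor genes gives 7.72 counts for control replicate 3, so the test does not decide. A response of the treated glands stays open, since 3 libraries against 3 cannot give an exact two-sided permutation p under 0.1, the value for the muscle score.

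Of 17 cartilage and 11 bone genes 4 and 3 were called, all higher with BMP-2, while 5 and 1 had negative changes. Neither list was called by camera with an estimated correlation (adjusted p = 0.148 and 0.176). Of the called genes, Dlx5 is also a BMP/SMAD response gene. Tissue that came along with the muscle could bring the called genes. Their index had a slope on the muscle index of -0.370 within groups, against 0.924 between groups, and from -0.632 to 1.03 when 1 library was left out, the highest without BMP-2 replicate 2, where the remaining treated libraries hardly differ in muscle (indices 1.29 and 1.37). BMP-2 replicate 2 had the least muscle of the treated libraries (index 0.344), yet 5 of the 7 genes were highest and 0 lowest in it; control replicate 3, with a muscle index of 0.153, had a cartilage and bone index of 0.129, between the other controls (0.122 and 0.146). These values go against a fixed share of both tissues, but the spread in muscle within each group rests on 1 library, which does not exclude a link. A piece of cartilage or bone primordium carried along independently of muscle also stays open: the 7 genes had a residual SD of 0.561 on the log2 scale over the treated libraries, which a response of gland mesenchyme to BMP-2, a hypothesis these libraries cannot separate from dissection, predicts too.

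Camera called the end bud and proacinar list downward with 0 of its 16 members called by edgeR (2 by DESeq2, 7 at an unadjusted p below 0.05 in edgeR), but not with an estimated correlation (adjusted p = 0.176) or the muscle covariate (0.163). A lower share of epithelium in the treated glands could give this. The values go against an equal fall of both lists, which such a share alone would give. The median log2 change was -0.34 for the 16 end bud genes and -0.11 for 17 general epithelial genes, a difference of -0.23 (two-sided permutation p over genes = 0.00182, genes not being independent). The difference of the list scores was -0.51, -0.32 and -0.44 in the treated libraries and between -0.04 and 0.07 in the controls (exact two-sided permutation p over libraries = 0.1, the lowest that 3 against 3 can give). The end bud list was taken up because camera called it lower in these data. The exact test over these libraries cannot reach a p of 0.05, so a lower share is not excluded. A delay of secretory differentiation under BMP-2 is a hypothesis that was not tested, and variation between litters in age stays open too.

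Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 155 changed genes, 138 higher, 17 lower and 133 with an absolute log2 change of at least 1, and the highest of the other splits gave 0 for each, so 1 split gave as many. For gene lists the real split gave 25 and the others 5 to 15. Camera with the preset correlation thus called lists also in splits with 0 called genes, so such a call alone is weak evidence.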
